A study of Mus musculus with 10 samples.

How the data were processed

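Expression was measured in 10 samples of mouse cells, 1 array each, in 5 groups of 2 arrays. Per the labels' protocols, cells of Six2-GFP transgenic mice on a C57BL6J and ICR background were sorted by flow cytometry, RNA was isolated with an RNeasy Plus Micro kit, cDNA was amplified with an Ovation Pico WTA kit and labelled with Cy3, and cultures were kept in conditioned medium for 8 or 19 days. The labels do not say whether cultured cells were sorted again or dissociated before RNA isolation, nor whether the replicates came from separate litters or cultures. They give the age at birth as P0, while the names of the deposited data give E19.5, and the labels were followed.

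The deposited values are intensities from Agilent Feature Extraction 11.5.1.1, per the file headers. The processed signal is background-subtracted and detrended within each array, and it was not normalized between arrays by the authors. The file of P0 progenitors replicate 2 had been saved again with 3 significant digits and with 62 gene names turned into dates, so names were taken from another array of the same design. Control spots were left out, and spots marked as outliers by the extraction software were treated as missing. No pseudocount was used.

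Each array's log2 intensity was reduced by its own 75th percentile over 59305 non-control spots, and the spots of a probe were averaged, which gave 55681 probes. Symbols were assigned to 28026 probes through RefSeq accessions, to 3418 through a current symbol and to 295 through a synonym, and 23942 kept the name in the file. A gene was represented by its probe with the highest mean, and genes were tested when a probe was well above background on both arrays of at least 1 group. This left 26253 of 34607 names, 17379 of them with a RefSeq symbol. Probe positions are those of the array design on mouse assembly mm9. Where no probe of a gene was well above background on either array of 1 of the groups compared, the fold is a lower bound, with that group's values raised to the lowest signal well above background on each array.

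Groups were compared with limma 3.58.1 in R 4.3.3 (the data.table package, version 1.17.8, read the tables). A mean per group was fitted to all 10 arrays, with an intensity trend in the moderation, 5 residual and 2.49 prior degrees of freedom, and Benjamini-Hochberg adjustment within each of 7 comparisons at 0.05, 2-sided. In each comparison, 30 gene lists were tested with camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry. List members were also adjusted over the list alone. The groups, comparisons, lists, tests and the alternatives named as planned were chosen before the data were examined. The lists were written from general knowledge, and some share genes.

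Genes named in the text were picked by a rule. In each comparison it took the 8 largest rises and the 8 largest falls among called genes with an ordinary symbol, well above background on all 4 arrays and with groups that did not overlap. It added the 4 highest and 4 lowest bounds, up to 4 members of a described list that passed and 2 that did not, and Six2, Cited1, Eya1, Osr1, Pax2, Wt1, Sall1, Wnt4 and Lhx1 in every comparison. The text names a selection from the top of each ranking. Fgf9, Aldh1a2 and Foxd1, the single members of their lists that moved against the rest, and the genes with opposite calls at the 2 culture times were named after their values were seen.

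The procedure was tested on simulated data built with the fitted spread of each gene. In 8-day culture against E11.5 progenitors it called 4 of 67 genes changed by 1 log2 unit (5.97%), 22 of 67 changed by 2 (32.8%) and 38 of 66 changed by 3 (57.6%), with 1 false call among 65, and called no gene in an unchanged comparison. A gene that did not pass may therefore have changed by several fold. The simulation gave every group the same spread, while replicates in the data differed by 0.833 in P0 progenitors and by 1.22 in E11.5 progenitors. Its number of false calls need not hold for the data. A fit of 8-day culture and E11.5 progenitors alone called 0 genes, against 1261 in the fit of all groups. Arrays well above background on 60.4% to 69.8% of spots, and their number, limit the precision.

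Alternatives were quantile normalization, normexp background correction with an offset of 50, no filter, a filter on all arrays, a floor on low values, the mean of a gene's probes, no intensity trend, robust moderation, a block for replicate number, a block for slide, a fit of the compared groups alone, leaving out each array, and a threshold of at least 1 log2 unit. Fits to the arrays of 1 slide and a limit on the genes of the progenitor sets were added after seeing the data. Slide 1 held all freshly sorted cells and 8-day culture replicate 1, and slide 2 held 8-day culture replicate 2 and both 19-day arrays, so that slide and group are told apart through the 8-day pair alone. With a slide block, 8-day culture replicate 1 alone is thus set against freshly sorted cells, and replicate 2 alone against 19-day culture. Groups of 2 arrays are too few for counts over other splits of the samples.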

Results

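Gene expression was measured on 10 single-colour Agilent mouse arrays, 2 for each of 5 groups of cells from mice that carry a Six2-GFP transgene. Six2 is a transcription factor that keeps nephron progenitors in their undifferentiated state, and the cells were sorted by flow cytometry for GFP. E11.5 progenitors and P0 progenitors were GFP-positive cells taken at the E11.5 stage and at birth, and P0 non-progenitors were the GFP-negative cells at birth. Birth is the age given in the labels, while the names of the deposited data give E19.5 for these 4 samples. The 8-day culture and the 19-day culture held E11.5 GFP-positive cells kept in conditioned medium for those times. Each array had 59305 non-control spots, of which 60.4% to 69.8% were well above background, and the intensity at the 75th percentile ran from 220.4 to 340.6. No spot was saturated. The number of arrays limits the precision.

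The arrays fell into their groups. Over 26253 tested genes, the root mean square difference of log2 values averaged 1.00 between replicates and 1.5 between arrays of different groups. Replicates differed by 0.833 in P0 progenitors and by 1.22 in E11.5 progenitors. The first principal component (28.5% of the variance) placed P0 non-progenitors opposite E11.5 progenitors, and the second (24.6%) placed 19-day culture opposite P0 non-progenitors. By this measure the 8-day culture lay nearest to P0 progenitors (1.31) and 19-day culture nearest to 8-day culture (1.36). The measure takes in the replicate spread, which was largest in E11.5 progenitors. These lay 1.41 from 8-day culture, so whether 8-day culture was nearer to P0 or to E11.5 progenitors is not settled.

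**Figure D1:**
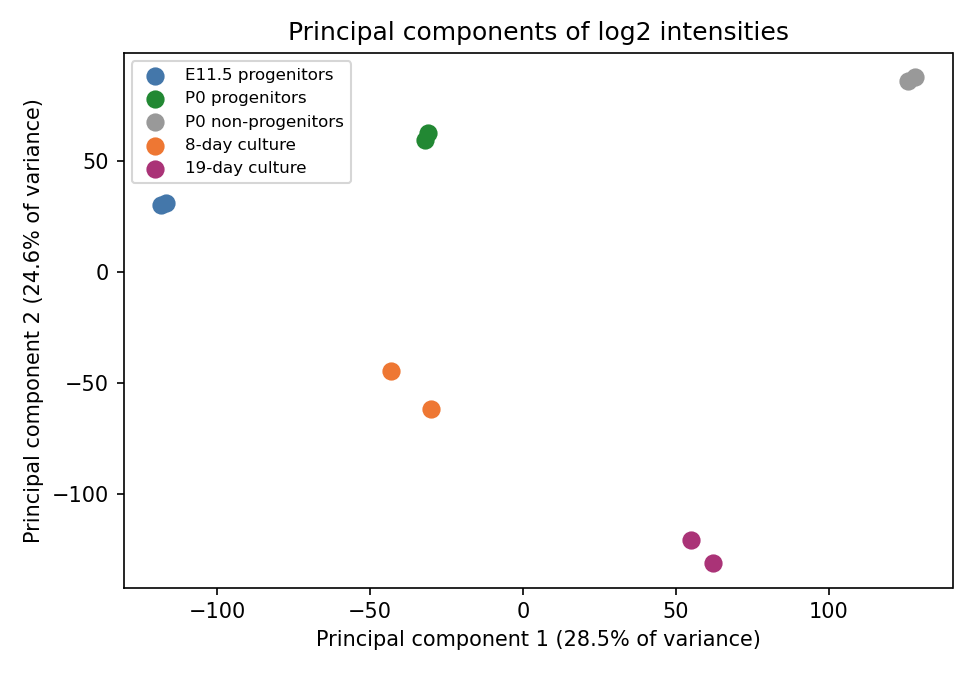
Principal components 1 and 2 of the log2 intensities of 26253 genes, each point 1 array, coloured by group. The 2 arrays of each group lie side by side, and 19-day culture has the lowest values on component 2, at -131 and -120.4.

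What distinguishes progenitors from the other sorted cells at birth was asked by setting P0 progenitors against P0 non-progenitors (n = 2 arrays each). Six2 was 193-fold higher in progenitors (log2 change 7.59 ± 0.71 SE, adjusted p = 0.00172). Its tested probe, at chromosome 17 from 86083634 to 86083693 (mm9), was well above background on 1 of the 2 P0 non-progenitor arrays. These read -2.26 and -4.54, so that the fold is not firm. Cited1, a cofactor of uninduced progenitors, was 29.6-fold higher (log2 change 4.89 ± 0.53 SE, adjusted p = 0.00278), Osr1 10.2-fold higher and Wnt4, the signal that starts nephron differentiation, 13.4-fold higher (log2 change 3.74 ± 0.59 SE, adjusted p = 0.0106). Pax2 was 3.93-fold higher and Wt1 2.44-fold higher. With any 1 array left out the calls of Osr1 and Wnt4 were lost in all 4 fits and that of Wt1 in 3. Sall1 (log2 change 2.44 ± 0.72 SE, adjusted p = 0.0899) and Lhx1 (log2 change -0.09 ± 0.24 SE, adjusted p = 0.89) did not pass. The single probe of Eya1 read between 9.32 and 9.63 on the log2 scale in every group and passed in no comparison. It read 9.24 and 9.40 even in P0 non-progenitors, so whether this flat and high probe reports Eya1 is not known. The tested Lhx1 probe also varied little, from 0.537 to 1.47 over all arrays, so whether it reports Lhx1 is not known either. The largest rises among genes above background on all 4 arrays were those of Amph (66.3-fold higher), Mrln (35.8-fold higher), Cxxc4 (33.7-fold higher), Col2a1 (33.4-fold higher) and Bmper, a BMP-binding protein (29.9-fold higher). Nell1 was at least 201-fold higher, Vat1l at least 61.8-fold higher and Fgf20, a growth factor that keeps progenitors alive, at least 57-fold higher. The largest falls were those of Penk (159-fold lower), Cd93 (122-fold lower), Fabp4 (115-fold lower) and Spink1 (99-fold lower). S100a9, a neutrophil protein, was at least 228-fold lower, and Hnf4a, a regulator of the proximal tubule, at least 85-fold lower.

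Genes of differentiated kidney cells were lower as groups in P0 progenitors. Of the proximal tubule list 13 of 17 measured members fell and 4 did not pass (14 fell and 1 rose adjusted over the list alone, camera adjusted p = 2.8e-13). Slc27a2 was 40.9-fold lower and Slc22a6 34.7-fold lower. In the loop of Henle and distal tubule list 7 of 13 measured members fell and 6 did not pass (10 fell adjusted over the list alone, camera adjusted p = 9.3e-09). Tfap2b was 20.1-fold lower and Umod 30.0-fold lower. For the ureteric bud and collecting duct 8 of 13 measured members fell and 5 did not pass (11 fell adjusted over the list alone, camera adjusted p = 1e-10), including Aqp3 (14-fold lower) and Wnt9b (14.6-fold lower). The podocyte list behaved likewise: 6 of 14 measured members fell and 8 did not pass (8 fell and 1 rose adjusted over the list alone, camera adjusted p = 1.1e-06). Podxl was at least 72.6-fold lower and Tcf21 3.83-fold lower. Among epithelial junction and keratin genes 9 of 13 measured members fell and 4 did not pass (13 fell adjusted over the list alone, camera adjusted p = 2.8e-13). Cdh16 was 16.8-fold lower. Other cell types in the negative gate showed the same direction. Endothelial genes: 11 of 15 measured members fell and 4 did not pass (12 fell adjusted over the list alone, camera adjusted p = 2.8e-13). Tie1 was at least 62.1-fold lower and Pecam1 30.6-fold lower. Renal stroma genes: 1 of 14 measured members rose, 8 fell and 5 did not pass (1 and 10 changed adjusted over the list alone, camera adjusted p = 1e-08). Col3a1 was 79-fold lower and Ren1, which encodes renin, 97.7-fold lower. The member that rose was Aldh1a2 (5.13-fold higher). Macrophage and leukocyte genes: 10 of 16 measured members fell and 6 did not pass (11 fell adjusted over the list alone, camera adjusted p = 2.6e-08). Fcer1g was 12.3-fold lower. Erythroid genes: 4 of 9 measured members fell and 5 did not pass (6 fell adjusted over the list alone, camera adjusted p = 2.2e-05, adjusted p = 0.077 with an estimated correlation). Hbb-b2 was 38.1-fold lower and Hba-a1 53-fold lower.

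Progenitor genes moved the other way. Of the nephron progenitor list 9 of 24 measured members rose, 1 fell and 14 did not pass (14 and 1 changed adjusted over the list alone, camera adjusted p = 2.6e-08). Uncx was 3.84-fold higher, while Fgf9 was 9.66-fold lower. Fgf9 read -4.19 and -6.45 in P0 progenitors, above background on 1 of the 2 arrays, so that its fold is not firm (log2 changes of -4.403 to -2.141 without 1 array). Of the posterior Hox genes, which pattern the kidney-forming mesoderm, 5 of 12 measured members rose and 7 did not pass (7 rose adjusted over the list alone, camera adjusted p = 0.0025, adjusted p = 0.055 with an estimated correlation). Hoxc10 was 4.78-fold higher and Hoxa10 2.05-fold higher. Of the cell cycle list 4 of 27 measured members rose and 23 did not pass (6 rose adjusted over the list alone, camera adjusted p = 2.5e-06, adjusted p = 0.15 with an estimated correlation). Mcm4 was 2.2-fold higher, Mcm7 2.72-fold higher and Mki67 2.28-fold higher. In all, 1112 genes were higher and 1091 lower by limma, 50.5% higher among those called, and 16 of 30 lists were called by camera, 9 of them also with an estimated correlation. With quantile scaling 1697 genes were called and 34.9% of them were higher, while with a filter above background on all arrays 68% of 1435 were. All 4 arrays were on slide 1, whose arrays alone gave 2353. The count was 676 without P0 progenitors replicate 1, 609 without replicate 2, 853 without P0 non-progenitors replicate 1 and 759 without replicate 2.

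**Figure D2:**
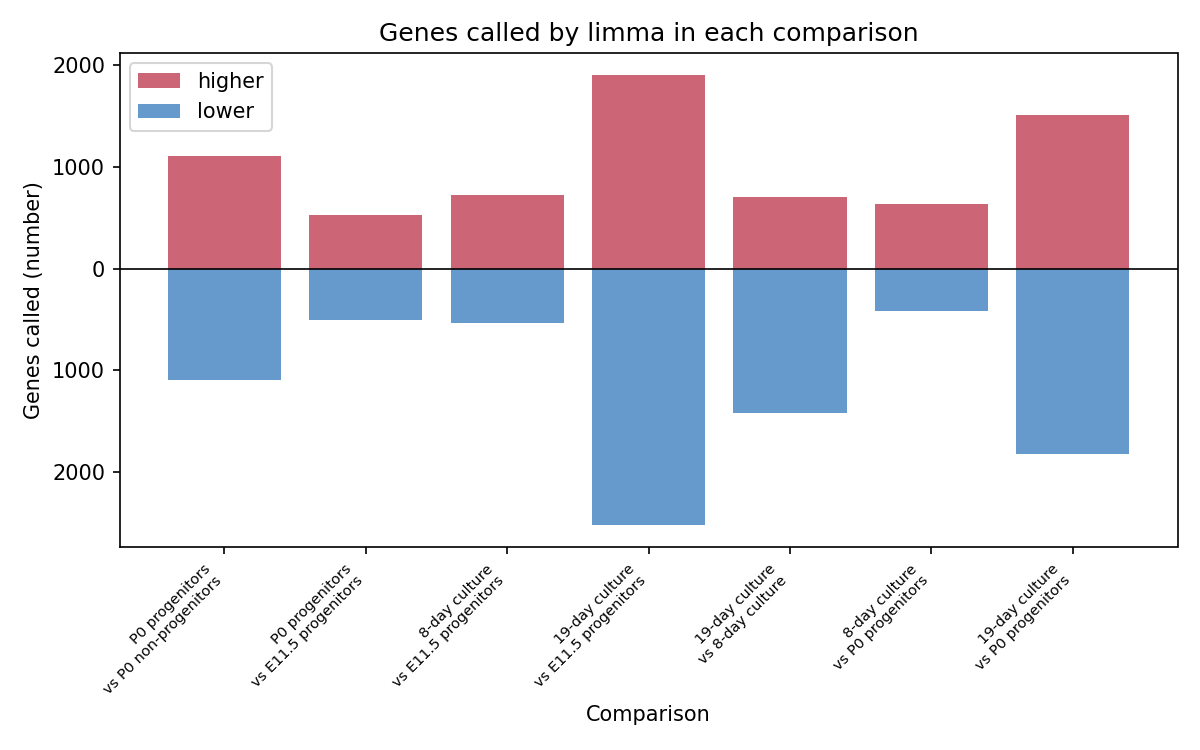
Number of genes called higher (upward bars) and lower (downward bars) in each of the 7 comparisons by limma at an adjusted p under 0.05, out of 26253 tested. The counts are largest for 19-day culture against E11.5 progenitors, at 1899 and 2517.

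How progenitors differ between the start of kidney development and birth was asked with P0 progenitors against E11.5 progenitors (n = 2 arrays each). Among core progenitor genes, Six2 (log2 change -0.57 ± 0.71 SE, adjusted p = 0.717), Osr1 (log2 change -1.20 ± 0.72 SE, adjusted p = 0.423), Pax2 (log2 change 0.81 ± 0.23 SE, adjusted p = 0.103), Sall1 (log2 change 0.08 ± 0.72 SE, adjusted p = 0.963) and Cited1 (log2 change 2.46 ± 0.53 SE, adjusted p = 0.0505) did not pass. Wnt4 was 9.99-fold higher at birth (log2 change 3.32 ± 0.59 SE, adjusted p = 0.0273), a call lost in 3 of 4 fits without 1 array. Fetal RNA-binding and chromatin proteins that hold cells in an early developmental state fell. In the Lin28 and fetal RNA-binding list 6 of 8 measured members fell and 2 did not pass (8 fell adjusted over the list alone, camera adjusted p = 9.4e-08, adjusted p = 0.081 with an estimated correlation). Hmga2 was 7.2-fold lower, Lin28b at least 5.92-fold lower and Igf2bp3 19.1-fold lower. The largest rises were those of Sema3g (40.3-fold higher), Cyria (32-fold higher) and Lama4 (29.5-fold higher). The largest falls were those of Moxd1 (31.5-fold lower), Zmat4 (28-fold lower) and Crispld2 (23.6-fold lower). S100g, a calcium-binding protein of the distal nephron, was at least 137-fold higher, Tfcp2l1 at least 91.2-fold higher and Fxyd2 at least 86.5-fold higher. Embryonic globins were lower, Hbb-y at least 491-fold lower and Hba-x at least 40.0-fold lower, while the adult globin Hbb-b2 was 7.55-fold higher.

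Genes of nephron differentiation were higher at birth as groups, and so, less firmly, were those of some other kidney cell types. The tubule, collecting duct, endothelial and junction genes named below read lower in P0 progenitors than in P0 non-progenitors. So did S100g, Tfcp2l1, Fxyd2 and Hbb-b2. Umod read -0.44 and -0.80 against 4.03 and 4.55, while Wnt4 went the other way, at 5.04 and 5.12 against 1.32 and 1.37. Sorted cells were measured in bulk, so which cells in the P0 sort carried these transcripts was not told apart. Of the pretubular aggregate and renal vesicle list 4 of 16 measured members rose and 12 did not pass (6 rose adjusted over the list alone, camera adjusted p = 6.9e-06, adjusted p = 0.081 with an estimated correlation). Ccnd1 was 6.65-fold higher and Jag1, a Notch ligand, 7.73-fold higher. In the loop of Henle and distal tubule list 4 of 13 measured members rose and 9 did not pass (6 rose adjusted over the list alone, camera adjusted p = 3.3e-06, adjusted p = 0.081 with an estimated correlation). Slc12a1 was at least 16.6-fold higher and Umod at least 14.4-fold higher. Of proximal tubule genes 2 of 17 measured members rose and 15 did not pass (2 rose adjusted over the list alone, camera adjusted p = 0.00037, adjusted p = 0.081 with an estimated correlation). Spp2 was at least 32.3-fold higher. In the podocyte list at birth 1 of 14 measured members rose and 13 did not pass (4 rose adjusted over the list alone, camera adjusted p = 0.0053, adjusted p = 0.11 with an estimated correlation). Of the ureteric bud and collecting duct genes 1 of 13 measured members rose and 12 did not pass (1 rose adjusted over the list alone, camera adjusted p = 0.047, adjusted p = 0.5 with an estimated correlation), namely Aqp3 (6.23-fold higher). That list's call was lost in 2 of 4 fits without 1 array (median 0.185 to 1.42), and its mean on P0 progenitors replicate 2 (-0.52) lay below that on E11.5 progenitors replicate 2 (-0.37). Of the endothelial genes 1 of 15 measured members rose and 14 did not pass (1 rose adjusted over the list alone, camera adjusted p = 0.047, adjusted p = 0.46 with an estimated correlation), namely Cldn5 (12.1-fold higher), with the call lost in 3 of 4 fits without 1 array and a median there of -0.0779 to 0.844. Of the epithelial junction and keratin genes at birth 2 of 13 measured members rose and 11 did not pass (5 rose adjusted over the list alone, camera adjusted p = 0.0013, adjusted p = 0.13 with an estimated correlation), among them Cdh16 (10.8-fold higher). Glycolysis and hypoxia genes moved down: 6 of 16 measured members fell and 10 did not pass (8 fell and 1 rose adjusted over the list alone, camera adjusted p = 5.4e-06, adjusted p = 0.13 with an estimated correlation). Ldha was 4.14-fold lower (log2 change -2.05 ± 0.11 SE, adjusted p = 0.000664), Aldoa 3.19-fold lower and Pgk1 2.51-fold lower. Of cholesterol synthesis genes 1 of 16 measured members rose, 4 fell and 11 did not pass (1 and 8 changed adjusted over the list alone, camera adjusted p = 0.0034, adjusted p = 0.13 with an estimated correlation). The 1 that rose was Sc5d (3.8-fold higher). Of the imprinted growth genes 3 of 12 measured members fell and 9 did not pass (3 fell adjusted over the list alone, camera adjusted p = 0.0011, adjusted p = 0.081 with an estimated correlation), namely Dlk1 (12.2-fold lower), Cdkn1c (9.6-fold lower) and Peg3 (2.41-fold lower). By limma 532 genes were higher and 506 lower (51.3% higher, or 65.3% under quantile scaling, with 916 calls). Camera called 14 lists, none with an estimated correlation, where 9 lists had an unadjusted p under 0.05. All 4 arrays were on slide 1, whose arrays alone gave 1095 genes. The count was 116 without P0 progenitors replicate 1, 118 without replicate 2 and 671 without E11.5 progenitors replicate 1.

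**Figure D3:**
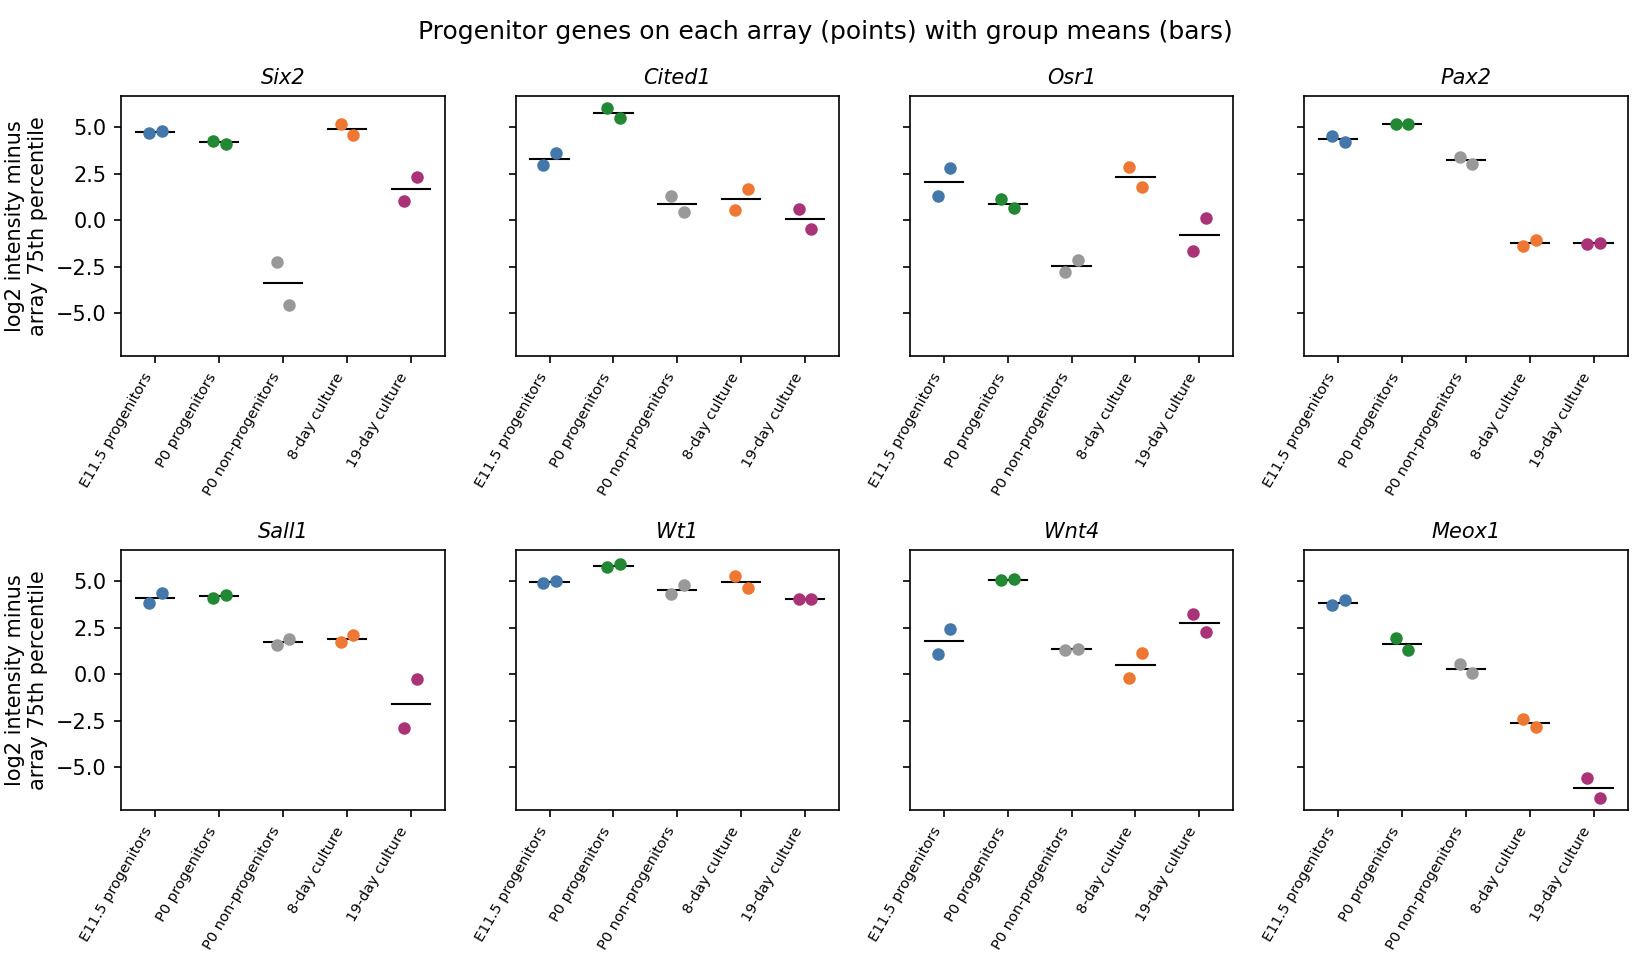
Log2 intensity, relative to each array's 75th percentile, of 8 progenitor genes on each of the 10 arrays, with a bar at each group's mean. Pax2 is low in both cultures, with a change of -5.61 at 8 days, while Six2 is low in P0 non-progenitors.

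What 8 days of culture changed was asked against the E11.5 progenitors from which the cultures began (n = 2 arrays each). Six2 (log2 change 0.15 ± 0.71 SE, adjusted p = 0.945), Osr1 (log2 change 0.24 ± 0.72 SE, adjusted p = 0.904) and Wt1 (log2 change -0.01 ± 0.24 SE, adjusted p = 0.989) did not pass. Pax2, a transcription factor of the whole nephron lineage, was 48.7-fold lower (log2 change -5.61 ± 0.23 SE, adjusted p = 0.000176), and each of its 3 probes was lower, by at least 3.42 log2 units. The tested probe lies at chromosome 19 from 44909895 to 44909954 (mm9). Meox1 was 89-fold lower and Bmp7 5.06-fold lower, the latter call lost in 3 of 4 fits without 1 array. Cited1 (log2 change -2.20 ± 0.53 SE, adjusted p = 0.0621) and Sall1 (log2 change -2.20 ± 0.72 SE, adjusted p = 0.14) did not pass. The largest rises were those of S100a6 (95.2-fold higher), Mt1, a metallothionein (87.8-fold higher), and Lox, which cross-links collagen (68.2-fold higher). Cyp1b1 was at least 124-fold higher and Aldh1a3 at least 87.6-fold higher. After Hbb-y (222-fold lower), the largest falls were those of Fosb (134-fold lower), Meox1 and Pax2. Foxc2 was at least 813-fold lower, Bmper at least 86.5-fold lower and Hspa1a, a heat shock protein, at least 76.5-fold lower.

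As a group, progenitor genes were lower. Of the nephron progenitor list 1 of 24 measured members rose, 3 fell and 20 did not pass (1 and 5 changed adjusted over the list alone, camera adjusted p = 0.0029, adjusted p = 0.18 with an estimated correlation). Of the immediate early and stress genes 4 of 13 measured members fell and 9 did not pass (7 fell adjusted over the list alone, camera adjusted p = 7.6e-06, adjusted p = 0.2 with an estimated correlation), namely Jun (13.6-fold lower), Hspa1a, Fosb and Fos (22.1-fold lower). Erythroid genes, a sign of blood cells, were lower too: 5 of 9 measured members fell and 4 did not pass (5 fell adjusted over the list alone, camera adjusted p = 1.5e-05, adjusted p = 0.18 with an estimated correlation), and their mean relative to all arrays was 2.23 on E11.5 progenitors replicate 1 and 0.24 on replicate 2. In the renal stroma list 5 of 14 measured members rose, 1 fell and 8 did not pass (7 and 1 changed adjusted over the list alone, camera adjusted p = 0.00016, adjusted p = 0.18 with an estimated correlation). Col3a1 was 19.6-fold higher and Col1a2 29-fold higher, while Foxd1 was 241-fold lower. Foxd1 read -6.16 and -2.63 on the 2 culture arrays, the first not above background, and its call was lost without 8-day culture replicate 1 or E11.5 progenitors replicate 1. Of the glycolysis and hypoxia genes 5 of 16 measured members rose and 11 did not pass (10 rose adjusted over the list alone, camera adjusted p = 1.5e-06, adjusted p = 0.18 with an estimated correlation). Ndrg1 was 14.3-fold higher and Pgk1 1.86-fold higher. Of the LIF and STAT3 targets 4 of 12 measured members rose and 8 did not pass (6 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.018, adjusted p = 0.4 with an estimated correlation). Bcl3 was 60.3-fold higher, Stat3 7.42-fold higher and Osmr at least 13-fold higher. The list mean was 0.70 on 8-day culture replicate 1 and -0.52 on replicate 2, and the call was lost without 8-day culture replicate 1 or E11.5 progenitors replicate 2. Of the BMP and SMAD targets 3 of 11 measured members fell and 8 did not pass (4 fell adjusted over the list alone, camera adjusted p = 0.0043, adjusted p = 0.2 with an estimated correlation). Id1 was 7.39-fold lower and Id2 4.47-fold lower. Muscle and cartilage genes: 5 of 15 measured members rose, 2 fell and 8 did not pass (8 and 2 changed adjusted over the list alone, camera adjusted p = 0.0029, adjusted p = 0.2 with an estimated correlation). Actc1 was at least 48.3-fold higher and Tnnt1 33-fold higher. Of the cell cycle list 4 of 27 measured members fell and 23 did not pass (13 fell adjusted over the list alone, camera adjusted p = 6e-07, adjusted p = 0.2 with an estimated correlation). Mcm7 was 2.59-fold lower and Rrm2 2.85-fold lower. Of the Lin28 and fetal RNA-binding list 4 of 8 measured members fell and 4 did not pass (5 fell adjusted over the list alone, camera adjusted p = 5.8e-05, adjusted p = 0.18 with an estimated correlation). Hmga2 was 4.17-fold lower. The interferon and cytokine lists read apart on the 2 culture arrays, with means of 1.34 and -1.27 for interferon genes and 2.36 and -0.53 for cytokines.

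By limma 725 genes were higher and 536 lower in 8-day culture. Camera called 16 lists, none of them with an estimated correlation, where 7 had an unadjusted p under 0.05. The 8-day arrays were on different slides, and 631 genes were called with slide as a block. That fit and a fit to the arrays of slide 1 alone both rest on 8-day culture replicate 1 as the only 8-day array. Both gave a median log2 change over all genes of -0.0429, so they are not separate checks. The count was 368 without 8-day culture replicate 1, 629 without replicate 2 and 717 without E11.5 progenitors replicate 1.

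What 19 days of culture changed was asked against the same E11.5 progenitors (n = 2 arrays each). Six2 was 8.4-fold lower (log2 change -3.07 ± 0.71 SE, adjusted p = 0.0252), Sall1, a kidney transcription factor, 51.6-fold lower (log2 change -5.69 ± 0.72 SE, adjusted p = 0.00266), Pax2 49-fold lower (log2 change -5.62 ± 0.23 SE, adjusted p = 4.53e-05), Cited1 9.58-fold lower, Osr1 7.26-fold lower and Wt1 1.9-fold lower. Without 1 array the Six2 call was lost in 3 of 4 fits (log2 changes of -3.697 to -2.442), that of Osr1 in 2 and that of Wt1 in all 4. Meox1 was at least 384-fold lower and Bmp7 at least 39.3-fold lower. Wnt4 (log2 change 1.00 ± 0.59 SE, adjusted p = 0.305) and Lhx1 (log2 change 0.08 ± 0.24 SE, adjusted p = 0.857) did not pass. The largest rises included S100a6 (2580-fold higher), Mt1 (577-fold higher), the chemokine Cxcl5 (284-fold higher) and Plac8 (264-fold higher). Cxcl5 read 7.65 and 3.79 on the 2 culture arrays, and its call was lost without 19-day culture replicate 1 or E11.5 progenitors replicate 2. Ctla2a was at least 2740-fold higher, Bgn, a matrix proteoglycan, at least 1100-fold higher and Mmp3, a matrix protease, at least 855-fold higher. After Hbb-y (548-fold lower), the largest falls were those of Foxc2 (248-fold lower), Cd24a (203-fold lower) and Spock2 (127-fold lower). Without 1 array the log2 change of Cd24a ran from -9.314 to -6.018 and that of Foxc2 from -9.243 to -6.66. Rasef was at least 293-fold lower and Col2a1 at least 159-fold lower.

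Of the nephron progenitor list after 19 days 1 of 24 measured members rose, 15 fell and 8 did not pass (2 and 16 changed adjusted over the list alone, camera adjusted p = 1.3e-06). Of the cell cycle genes 19 of 27 measured members fell and 8 did not pass (20 fell adjusted over the list alone, camera adjusted p = 7.7e-13, adjusted p = 0.1 with an estimated correlation). Mcm7 was 6.32-fold lower and Cdc6 8.91-fold lower. Inhibitors of the cell cycle moved the other way: of the Cdk inhibitor and p53 targets 10 of 15 measured members rose, 1 fell and 4 did not pass (10 and 1 changed adjusted over the list alone, camera adjusted p = 4.8e-06, adjusted p = 0.1 with an estimated correlation). Cdkn2a was at least 81.6-fold higher and Cdkn2b at least 105-fold higher, while Cdkn1c was 11.4-fold lower. In the renal stroma list 8 of 14 measured members rose, 1 fell and 5 did not pass (9 and 1 changed adjusted over the list alone, camera adjusted p = 3e-06). Col3a1 was 148-fold higher and Pdgfra at least 79.1-fold higher, while Foxd1 was 124-fold lower. Foxd1 was above background on 1 of the 2 arrays, and its log2 change ran from -8.388 to -5.516 without 1 array. Of the YAP and SRF targets, genes of the cytoskeleton and of stretched cells, 9 of 12 measured members rose and 3 did not pass (11 rose adjusted over the list alone, camera adjusted p = 5.7e-07, adjusted p = 0.1 with an estimated correlation). Thbs1 was 36.8-fold higher, Acta2 109-fold higher and Ccn2 88.6-fold higher. Of the LIF and STAT3 targets at this time 6 of 12 measured members rose and 6 did not pass (8 rose adjusted over the list alone, camera adjusted p = 9.7e-06, adjusted p = 0.12 with an estimated correlation). Osmr was at least 530-fold higher. Of the interferon response genes 7 of 11 measured members rose and 4 did not pass (7 rose adjusted over the list alone, camera adjusted p = 4.3e-06, adjusted p = 0.3 with an estimated correlation). Bst2 was 12.3-fold higher and Isg15 58.7-fold higher. Of the inflammatory cytokines 4 of 8 measured members rose and 4 did not pass (6 rose adjusted over the list alone, camera adjusted p = 0.00079, adjusted p = 0.22 with an estimated correlation). Ccl2 was 21.3-fold higher and Lcn2 8.33-fold higher. On the 2 arrays the cytokine list averaged 5.02 and 2.02, and the interferon list 1.12 and 4.15. Of the imprinted growth genes at 19 days 1 of 12 measured members rose, 7 fell and 4 did not pass (1 and 7 changed adjusted over the list alone, camera adjusted p = 0.0052, adjusted p = 0.1 with an estimated correlation). Igf2, a fetal growth factor, was 13.4-fold lower and H19 3.55-fold lower. Of the mitochondrial respiration genes 9 of 14 measured members fell and 5 did not pass (11 fell adjusted over the list alone, camera adjusted p = 3.3e-05, adjusted p = 0.12 with an estimated correlation). Cycs was 2.08-fold lower. Erythroid genes were lower as at 8 days: 5 of 9 measured members fell and 4 did not pass (5 fell adjusted over the list alone, camera adjusted p = 0.00034, adjusted p = 0.12 with an estimated correlation).

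By limma 1899 genes were higher and 2517 lower at 19 days (43% higher). The excess of falls was absent under quantile scaling (1969 higher and 1856 lower) and among changes of at least 1 log2 unit (1784 and 1770). Camera called 15 lists, 2 of them (nephron progenitor and renal stroma) also with an estimated correlation. The 19-day arrays were on slide 2 and the E11.5 arrays on slide 1. With slide as a block, estimated through the 8-day pair alone, 1489 genes were called, and without 19-day culture replicate 1 the count was 2374.

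**Figure D4:**
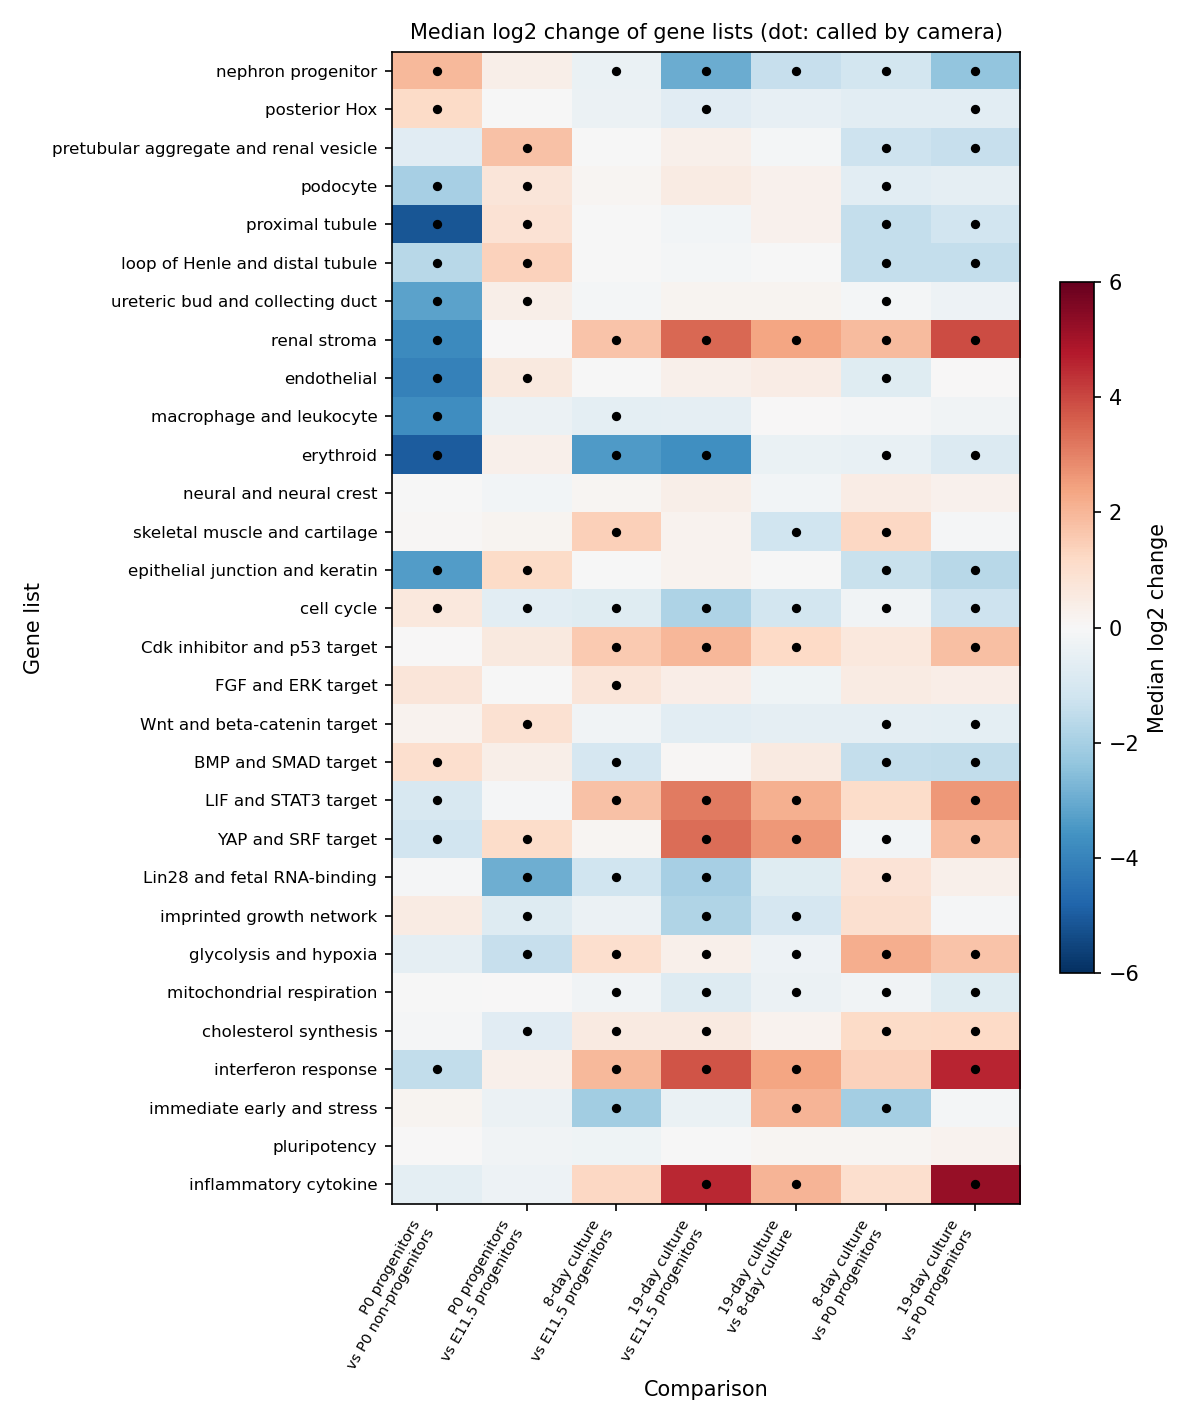
Median log2 change of the measured members of each of 30 gene lists (vertical axis) in the 7 comparisons (horizontal axis), with a dot where camera called the list. The renal stroma list has a median of 3.46 and the nephron progenitor list of -2.96 in 19-day culture against E11.5 progenitors.

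Whether longer culture moved the cells further was asked with 19-day against 8-day culture (n = 2 arrays each). Six2 was 9.31-fold lower at 19 days (log2 change -3.22 ± 0.71 SE, adjusted p = 0.0352), Sall1 11.2-fold lower and Osr1 8.6-fold lower, while Pax2 (log2 change -0.01 ± 0.23 SE, adjusted p = 0.987) and Cited1 (log2 change -1.06 ± 0.53 SE, adjusted p = 0.296) did not pass. Wnt4 (log2 change 2.30 ± 0.59 SE, adjusted p = 0.0577) and Wt1 (log2 change -0.91 ± 0.24 SE, adjusted p = 0.0635) also missed the threshold. Without 1 array the calls of Six2 and Osr1 were lost in 3 of 4 fits and that of Sall1 in 2, where the Sall1 change ran from -4.802 to -2.172. The largest rises were those of Kng1 (109-fold higher), Plscr2 (81.6-fold higher), Fosb (68.2-fold higher), Col6a2 (54.5-fold higher) and Ccn1 (52.2-fold higher). Ctla2b was at least 290-fold higher and Bmper at least 115-fold higher. The largest falls were those of Cd24a (74.6-fold lower), Fat3 (36.3-fold lower), Fxyd6 (33.2-fold lower) and Aldh1a3, which makes retinoic acid (30.8-fold lower). Rasef was at least 240-fold lower and Actc1, a sarcomeric actin, at least 83.4-fold lower.

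Between the 2 culture times, of the nephron progenitor list 7 of 24 measured members fell and 17 did not pass (10 fell adjusted over the list alone, camera adjusted p = 1.7e-05, adjusted p = 0.096 with an estimated correlation). Bmp7 was at least 7.77-fold lower and Spock2 16.6-fold lower. Of the muscle and cartilage genes 6 of 15 measured members fell and 9 did not pass (8 fell adjusted over the list alone, camera adjusted p = 1.5e-05, adjusted p = 0.12 with an estimated correlation). Col2a1 was at least 38.4-fold lower and Tnnt1 11.2-fold lower. Cell cycle genes: 9 of 27 measured members fell and 18 did not pass (17 fell adjusted over the list alone, camera adjusted p = 2.5e-09, adjusted p = 0.12 with an estimated correlation). Mcm6 was 3.19-fold lower. Of the Cdk inhibitor and p53 targets between these times 6 of 15 measured members rose, 1 fell and 8 did not pass (8 and 1 changed adjusted over the list alone, camera adjusted p = 8.7e-05, adjusted p = 0.16 with an estimated correlation). Cdkn2a was 38.3-fold higher, the p53 target Bax 2.22-fold higher and Cdkn1c 9.36-fold lower. YAP and SRF targets: 7 of 12 measured members rose and 5 did not pass (9 rose adjusted over the list alone, camera adjusted p = 3.2e-08, adjusted p = 0.12 with an estimated correlation). Thbs1 was 36.2-fold higher and Tagln 9.18-fold higher. Immediate early and stress genes, low at 8 days, were higher: 4 of 13 measured members rose and 9 did not pass (8 rose adjusted over the list alone, camera adjusted p = 1.5e-05, adjusted p = 0.25 with an estimated correlation). Jun was 4.01-fold higher and Fos 16.8-fold higher. The list mean was 1.12 on 19-day culture replicate 1 and -0.36 on replicate 2, and the Fos call was lost in 2 of 4 fits without 1 array. Renal stroma genes between these times: 5 of 14 measured members rose and 9 did not pass (8 rose adjusted over the list alone, camera adjusted p = 8.7e-05, adjusted p = 0.096 with an estimated correlation). Col1a1 was 16-fold higher and Pdgfra 32.8-fold higher. Imprinted growth genes: 6 of 12 measured members fell and 6 did not pass (7 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.00092, adjusted p = 0.12 with an estimated correlation). Igf2 was 9.88-fold lower and Mest 9.86-fold lower. The Mest call was lost in 2 of 4 fits without 1 array, where its log2 change ran from -4.641 to -1.964. By limma 701 genes were higher and 1417 lower (33.1% higher, or 45.2% under quantile scaling, with 1668 calls). Among changes of at least 1 log2 unit 651 were higher and 694 lower, and without the intensity trend 51.3% of 760 were higher. Camera called 13 lists, none with an estimated correlation, where 7 had an unadjusted p under 0.05. The count was 1704 with slide as a block, and limma called 0 genes on the 3 arrays of slide 2 alone, where 4767 genes had an unadjusted p under 0.05. It was 824 without 8-day culture replicate 2 and 916 without 19-day culture replicate 1.

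How far cells cultured from E11.5 resembled progenitors that stayed in the embryo until birth was asked with 8-day culture against P0 progenitors (n = 2 arrays each). Six2 (log2 change 0.72 ± 0.71 SE, adjusted p = 0.631), Osr1 (log2 change 1.44 ± 0.72 SE, adjusted p = 0.312) and Sall1 (log2 change -2.29 ± 0.72 SE, adjusted p = 0.134) did not pass. Pax2 was 85.6-fold lower in culture (log2 change -6.42 ± 0.23 SE, adjusted p = 0.000169), Cited1 25.2-fold lower and Wnt4 24.6-fold lower, the last 2 calls each lost in 2 of 4 fits without 1 array. The largest rises were those of Nav3 (95.8-fold higher), Nfib (50.5-fold higher) and Trib3 (35.6-fold higher), Myl1 was at least 208-fold higher and Syt13 at least 170-fold higher. The largest falls were those of Fosb (99.6-fold lower), Cldn11 (88.8-fold lower) and Pax2, and Foxc2 was at least 262-fold lower. Glycolysis and hypoxia genes were higher in culture: 11 of 16 measured members rose and 5 did not pass (16 rose adjusted over the list alone, camera adjusted p = 3.2e-16). Ldha was 4.23-fold higher (log2 change 2.08 ± 0.11 SE, adjusted p = 0.000471), Pgk1 4.67-fold higher and the glucose transporter gene Slc2a1 6.25-fold higher. Of the cholesterol synthesis genes 6 of 16 measured members rose and 10 did not pass (11 rose adjusted over the list alone, camera adjusted p = 4.2e-07). Sqle was 2.14-fold higher and Nsdhl 2.96-fold higher. Genes of the tubule were lower, and so, less firmly, were those of some other kidney cell types. Which cells in the P0 sort carried these transcripts was not told apart. In the loop of Henle and distal tubule list 5 of 13 measured members fell and 8 did not pass (6 fell adjusted over the list alone, camera adjusted p = 1.2e-06). Tmem52b was at least 17.6-fold lower. In the proximal tubule list 3 of 17 measured members fell and 14 did not pass (8 fell adjusted over the list alone, camera adjusted p = 6.4e-06). Spp2 was at least 29.8-fold lower. Among ureteric bud and collecting duct genes 1 of 13 measured members fell and 12 did not pass (2 fell adjusted over the list alone, camera adjusted p = 0.026, adjusted p = 0.3 with an estimated correlation), namely Aqp3 (7.42-fold lower), with the call lost in 2 of 4 fits without 1 array (median -1.02 to -0.0128). Among endothelial genes 1 of 15 measured members fell and 14 did not pass (1 fell adjusted over the list alone, camera adjusted p = 0.0076, adjusted p = 0.21 with an estimated correlation), namely Cldn5 (10.3-fold lower), with the call lost in 1 of 4 such fits (median -1.29 to 0.061). Of the epithelial junction and keratin genes in culture 3 of 13 measured members fell and 10 did not pass (5 fell adjusted over the list alone, camera adjusted p = 0.00035, adjusted p = 0.099 with an estimated correlation). Cdh16 was 9.76-fold lower. Among erythroid genes 3 of 9 measured members fell and 6 did not pass (4 fell adjusted over the list alone, camera adjusted p = 0.0038, adjusted p = 0.19 with an estimated correlation). Hbb-b2 was at least 22.4-fold lower. Of the BMP and SMAD targets in this comparison 4 of 11 measured members fell and 7 did not pass (5 fell adjusted over the list alone, camera adjusted p = 6.4e-06, adjusted p = 0.055 with an estimated correlation). Id1 was 5.79-fold lower. Of the nephron progenitor genes 2 of 24 measured members rose, 4 fell and 18 did not pass (2 and 10 changed adjusted over the list alone, camera adjusted p = 0.0002). By limma 632 genes were higher and 411 lower (60.6% higher, or 44.3% under quantile scaling, with 879 calls). Camera called 20 lists, 5 also with an estimated correlation. With slide as a block 483 genes were called and on slide 1 alone 465. The count was 125 and 127 without P0 progenitors replicate 1 or 2, and 404 and 482 without 8-day culture replicate 1 or 2.

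The same question was put for the longer culture with 19-day culture against P0 progenitors (n = 2 arrays each). Pax2 was 86.2-fold lower (log2 change -6.43 ± 0.23 SE, adjusted p = 6.38e-05), Sall1 54.8-fold lower, Cited1 52.6-fold lower, Wt1 3.46-fold lower and Wnt4 5.0-fold lower, the last call lost in all 4 fits without 1 array. Six2 (log2 change -2.50 ± 0.71 SE, adjusted p = 0.0598) and Osr1 (log2 change -1.66 ± 0.72 SE, adjusted p = 0.174) did not pass. The largest rises were those of S100a6 (318-fold higher), Col3a1 (223-fold higher) and Plac8 (143-fold higher), and Mmp3 was at least 793-fold higher. The largest falls were those of Spock2 (242-fold lower), Scube3 (149-fold lower) and Cd24a (109-fold lower), and Col2a1 was at least 259-fold lower. Of the nephron progenitor genes here 2 of 24 measured members rose, 11 fell and 11 did not pass (2 and 13 changed adjusted over the list alone, camera adjusted p = 1.9e-08). Renal stroma genes in this comparison: 8 of 14 measured members rose, 1 fell and 5 did not pass (9 and 1 changed adjusted over the list alone, camera adjusted p = 4.3e-06). Col1a1 was 137-fold higher. Of the cell cycle genes here 17 of 27 measured members fell and 10 did not pass (23 fell adjusted over the list alone, camera adjusted p = 9.6e-12, adjusted p = 0.096 with an estimated correlation). Mcm7 was 5.97-fold lower. Of the Cdk inhibitor and p53 targets here 7 of 15 measured members rose and 8 did not pass (10 rose adjusted over the list alone, camera adjusted p = 2.4e-05, adjusted p = 0.1 with an estimated correlation). Cdkn2a was at least 83.3-fold higher. Of the cholesterol synthesis genes here 9 of 16 measured members rose and 7 did not pass (12 rose adjusted over the list alone, camera adjusted p = 4.1e-07). Fdft1 was 3.78-fold higher. Of the loop of Henle and distal tubule genes 6 of 13 measured members fell and 7 did not pass (6 fell adjusted over the list alone, camera adjusted p = 5.7e-05). Tfap2b was at least 18.8-fold lower. Of the epithelial junction and keratin genes here 4 of 13 measured members fell and 9 did not pass (5 fell adjusted over the list alone, camera adjusted p = 0.014, adjusted p = 0.17 with an estimated correlation). Cdh16 was 8.74-fold lower. Among erythroid genes here 4 of 9 measured members fell and 5 did not pass (4 fell adjusted over the list alone, camera adjusted p = 0.0063, adjusted p = 0.17 with an estimated correlation). Hbb-b2 was at least 29.5-fold lower. By limma 1514 genes were higher and 1820 lower. Camera called 19 lists, 4 also with an estimated correlation. These groups share no slide, and with slide as a block 705 genes were called. The count was 935 and 961 without P0 progenitors replicate 1 or 2 and 1571 without 19-day culture replicate 1.

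The genes called higher or lower in P0 progenitors than in P0 non-progenitors were followed through culture as sets, in contrasts that share no array with that one. Of the 1112 higher entries 634 had a RefSeq symbol, against 977 of the 1091 lower ones. Quantile scaling called 592 higher, and the 6 set results kept their outcome under it. The 1112 genes higher in P0 progenitors than in P0 non-progenitors had a median log2 change of -0.53 at 19 days against E11.5 progenitors, and 544 of them fell and 26 rose (camera adjusted p = 3.35e-29, and 0.00362 with an estimated correlation, over 6 tests). From 8 to 19 days their median was -0.68, with 564 falls and 27 rises (camera adjusted p = 5.62e-43, and 0.00181 with an estimated correlation). At 8 days their median was 0.06, with 153 rises and 129 falls (adjusted p = 0.501). Limited to the 522 genes that differed by at least 1 log2 unit at birth, a limit added after seeing the data, the set had a median of -0.35 at 8 days (adjusted p = 1.65e-06), and with no intensity trend in limma -0.32 (adjusted p = 8.36e-06). The 1091 genes lower in P0 progenitors were higher at 8 days (median 0.17, adjusted p = 0.000235), at 19 days (0.47, adjusted p = 2.26e-10) and from 8 to 19 days (0.25, adjusted p = 1.07e-07). Camera with an estimated correlation gave adjusted p = 0.000745, 0.000158 and 0.00019, in that order.

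Whether culture moved genes the way development to birth did was asked across genes, which are not independent replicates. The log2 changes of P0 progenitors and of 8-day culture, both against E11.5 progenitors, correlated with Pearson's r = 0.502 and Spearman's rho = 0.474. Simulated unchanged groups that share the E11.5 arrays gave r = 0.50 over 100 draws. Sharing arrays of equal spread fixes that value in advance, so the match in r says nothing on its own. The covariance, which depends on the size of the changes, was 0.623 against 0.200 in the simulation, drawn with a spread pooled over all groups. The shared part depends on the spread of the E11.5 arrays, whose replicates differed most, by 1.22. The simulated covariance may thus be too low, and the excess over it does not measure shared change. Of the genes called in both, 213 were higher and 132 lower in both, where independent lists would share 14.7 and 10.3, and 5 and 8 went in opposite directions. The 2 comparisons share the E11.5 arrays, and a split would leave each with 1 of them, so part of the excess over independent lists can come from the shared arrays. In 19-day against 8-day culture, which share no array with the P0 comparison, the 532 genes higher at birth had a median of 0.34 (camera adjusted p = 2.72e-05, and 0.00582 with an estimated correlation). The 506 genes lower at birth had a median of -0.30 (adjusted p = 2.55e-11, and 0.0159 with an estimated correlation). The latter call was lost under quantile scaling (-0.05, adjusted p = 0.228), without the intensity trend (-0.08, adjusted p = 0.0834) and without P0 progenitors replicate 1 (-0.03) or replicate 2 (-0.16).

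Against E11.5 progenitors, 874 genes were called at both culture times, 410 higher and 421 lower at both, where independent lists would share 52.4 and 51.4. The log2 changes at the 2 times correlated across genes with r = 0.652, against 0.502 in simulated unchanged groups, and with a covariance of 1.13, against 0.201. These comparisons also share the E11.5 arrays, which fixes the simulated r in advance. Their simulated covariance may be too low for the reason given above.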

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

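The comparison of the 2 culture times and the fit with slide as a block were planned, while the search for opposite calls, the other tests in this part and the use of the slide block to weigh an explanation were chosen after the results were seen. Of 874 genes called at both culture times against E11.5 progenitors, 43 were called in opposite directions, which makes a difference between the times follow from the choice. They drew attention because the same contrast gave opposite effects at 2 times. Actc1, a sarcomeric actin, had a log2 change of -8.24 from 8 to 19 days, which is not a size, since no probe was above background at 19 days and the bound is at least 83.4-fold lower. Its call of -2.64 at 19 days sets 2 groups against each other that both lay at or near background. Ccn1, a matrix protein driven by YAP, had a log2 change of 5.71 between the times, after -3.86 at 8 days and 1.85 at 19 days. Ccnd1, a cyclin of the G1 phase, had 3.00 between the times, after -1.66 at 8 days and 1.34 at 19 days.

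Pax2 was low in 8-day culture while the Six2 value was close to that of E11.5 progenitors. A difference between slides would need no fall within a slide, but on the arrays of slide 1 alone the Pax2 change was -5.79 (3 arrays). There 8-day culture replicate 1 was the only culture array, so its spread is not known. Dilution by other cells would lower both genes alike, but the Six2 change exceeded the Pax2 change by 5.75 ± 0.745 SE, which argues against it as the whole cause. This difference restates the pattern that was picked out, so it is not a separate test. A single misleading probe is argued against by the 3 Pax2 probes, the smallest change of which was -3.42. A change in the cells during culture stays open as a hypothesis that was not tested.

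After 19 days stroma genes were higher and progenitor genes lower. With slide as a block over all 10 arrays the stroma list had a median change of 2.64 from 8 to 19 days (camera adjusted p = 8.94e-05), which argues against slides as the whole cause of the stromal rise between the cultures, although slide is told apart through the 8-day pair alone. Dilution of unchanged progenitors is not settled by the list as a whole. The other 21 list members above background in E11.5 progenitors had a median that differed from the Six2 change by -0.19 ± 1.2 SE, but members went both ways. Pax2 (-5.62), Meox1, Sall1, Bmp7 and Spock2 fell further than Six2, and Wt1 (-0.93) and Osr1 fell less. Genes also made by other cells would fall less. Pax2 was already low at 8 days, where the Six2 change exceeded the Pax2 change by 5.75 ± 0.745 SE. That same 8-day pattern argues against dilution as the whole cause for Pax2. Dilution alone would not lower Meox1, Sall1, Bmp7 or Spock2 further than Six2, but these were picked from the list by their falls. For the list as a whole dilution stays open. Growth of renal stromal cells remains open: of the 13 stroma genes above background in P0 non-progenitors 8 rose and Foxd1 fell. The sort for GFP before culture stands against such growth only in part. The sorted E11.5 cells read 5.51 and 3.87 for the globin Hbb-y and 3.83 and 3.20 for Foxd1, while Pdgfra read -6.16 and -6.28. Foxd1 is an unsure sign of stroma here, at 2.63 and 1.49 in P0 progenitors and 1.20 and 1.55 in P0 non-progenitors. The stroma list averaged -1.63 and -1.69 on the E11.5 arrays, relative to all arrays. No array held stromal cells alone to say what levels their share would need. A change of the cultured progenitors themselves also stays open, untested.

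Immediate early genes were low at 8 days, and at 19 days their list was not called. Within slide 1, which held 1 of the 8-day arrays, the list's median at 8 days was -1.63. This argues against a difference between slides, though it rests on a lone 8-day array. Stress from sorting, present in fresh cells alone, might leave both cultures low, and at 19 days the median was -0.397 (adjusted p = 0.609), with the 2 arrays apart at list means of 1.12 and -0.36. The labels do not say how cultured cells were harvested, so that stress at harvest cannot be told apart from a difference in culture time, which was not tested separately.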

How the results depend on the processing

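The fits to 1 slide and the limit on set genes were chosen after seeing the data; the other settings were planned. With 2 arrays per group, leaving out 1 array leaves a lone array that is assumed to vary like the other groups. Both comparisons of 19-day culture with freshly sorted cells lie wholly across slides. Where no cause is named below, the cause was not tested. Over 10 pairs of groups the correlation of replicate differences ran from -0.0138 to 0.0287. A value near 0 over all genes does not rule out that arrays were paired. The replicates numbered 2 of both P0 groups lacked Y-linked transcripts (Ddx3y at -6.24 and -6.78), and those numbered 1 held them. Pairing of the P0 arrays by replicate number thus stays open, and it was not fitted for the P0 groups alone. A block for replicate number gave 1965 genes for P0 progenitors against P0 non-progenitors, 786 against E11.5 progenitors, 1049 and 4180 for 8 and 19 days of culture against E11.5 progenitors, 1904 between the cultures, and 878 and 2969 for the cultures against P0 progenitors. Of 113 single list results, the call was lost in 4 under quantile normalization, 6 under normexp, 1 without a filter, 6 with a floor, 3 with the mean of probes, 10 with a slide block, 2 with a replicate block, 1 with the compared groups alone, 5 of 66 on slide 1 alone, 1 of 13 on slide 2 alone, 16 of 92 with a filter on all arrays and 37 of 452 fits that left out 1 array. None reversed. Robust moderation was not run for camera. Medians of all genes as reported lay between -0.125 and 0.134, and under normexp they were -0.165 for 19-day culture against E11.5 progenitors and -0.111 between the cultures.

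Limiting calls to at least 1 log2 unit left 1345 genes between the cultures. Apart from fits without 1 array or on 1 slide, the share of higher calls ran from 30.3% (no intensity trend) to 68% (filter on all arrays) in P0 progenitors against P0 non-progenitors and from 41.2% (compared groups alone) to 68% (no trend) against E11.5 progenitors. It ran from 51.8% (filter on all arrays) to 64.7% (no trend) at 8 days, 36.7% (that filter) to 51.5% (quantile) at 19 days and 27.9% (that filter) to 51.3% (no trend) between the cultures. Against P0 progenitors it was 44.3% (quantile) to 67.1% (that filter) at 8 days and 43.3% (replicate block) to 52.1% (no trend) at 19 days. An estimated correlation left 9 lists in P0 progenitors against P0 non-progenitors, 0 against E11.5 progenitors, 0 at 8 days and 2 at 19 days against E11.5 progenitors, 0 between the cultures, and 5 and 4 in 8-day and 19-day culture against P0 progenitors. A filter on all arrays, which tests fewer genes, gave 1435 genes in P0 progenitors against P0 non-progenitors, 9 lists against E11.5 progenitors, 9 at 8 days, 12 in 19-day culture against P0 progenitors, a developmental correlation of 0.525, and distances of 0.732 for replicates and 1.07 for different groups. Distances were 0.83 and 1.26 with a floor, and 0.539 and 0.872 with normexp, which also gave a correlation of 0.477.

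Without the intensity trend limma called 1266 genes in P0 progenitors against P0 non-progenitors, 447 against E11.5 progenitors, 541 at 8 days, 760 between the cultures and 491 in 8-day culture against P0 progenitors. The genes higher in P0 progenitors then had a median of -0.315 at 8 days (adjusted p = 8.36e-06), reversed from 0.0584. With the trend, the genes differing by at least 1 log2 unit at birth had a median of -0.349 (adjusted p = 1.65e-06). The genes lower at birth had a median between the cultures of -0.0838 (adjusted p = 0.0834) without the trend and -0.0475 (adjusted p = 0.228) under quantile normalization. Eya1 at 19 days against E11.5 progenitors had a log2 change of 0.11 and passed (adjusted p = 0.033) under quantile normalization, against -0.28 without it, which did not.

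Fitting the compared groups alone gave 434 genes for P0 against E11.5 progenitors, 1297 at 19 days and 349 in 8-day culture against P0 progenitors, and limma then called 0 at 8 days (3951 at an unadjusted p under 0.05) and 0 between the cultures (4986). A slide block gave 631 genes at 8 days, 1489 at 19 days, 483 and 705 in the cultures against P0 progenitors, and a correlation of 0.456. In 8-day culture against fresh cells it leaves replicate 1 as the only 8-day array, as slide 1 alone does. On slide 1 alone limma called 687 genes at 8 days and 465 in 8-day culture against P0 progenitors, with a correlation of 0.456, and on slide 2 alone 0 between the cultures (4767 at an unadjusted p under 0.05).

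Leaving out 1 array gave 609 to 853 genes in P0 progenitors against P0 non-progenitors, 116 to 870 against E11.5 progenitors, 368 to 887 at 8 days, 2374 to 3378 at 19 days, 824 to 1761 between the cultures, 125 to 482 and 935 to 2309 in the cultures against P0 progenitors, a correlation of 0.455 to 0.624, and a median of -0.379 to -0.0286 for the genes lower at birth between the cultures.

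Of 262 results for single genes named in the text, 98 lost the call with the compared groups alone, 36 with a slide block, 26 without the intensity trend, 9 with a replicate block and 34 of 39 on slide 2 alone, and 188 of 1048 fits to them lost it with 1 array left out, where fewer arrays widen the spread. Calls lost in each of the 4 fits without 1 array were those of Fabp4, Fgf20, Hoxa10, Mrln, Nell1, Osr1, Tcf21 and Wnt4 in P0 progenitors against P0 non-progenitors, Igf2bp3, Moxd1, Peg3, Sc5d and Tnfrsf19 in P0 against E11.5 progenitors, Osmr at 8 days, Wt1 at 19 days, Myl1, Nsdhl and Trib3 in 8-day culture against P0 progenitors, and Wnt4 in 19-day culture against P0 progenitors. Calls lost in 3 of the 4 were those of Bmper, Fgf9, Mki67 and Wt1 in P0 progenitors against P0 non-progenitors, Hbb-b2, Jag1, Lin28b and Wnt4 in P0 against E11.5 progenitors, Bmp7, Dusp6 and Fos at 8 days, Fosl1, Lcn2, Pax8 and Six2 at 19 days, Osr1, Six2, Spock2 and Tnnt1 between the cultures, and Fosb, Sqle and Syt13 in 8-day culture against P0 progenitors. Between these fits the log2 change moved by over 2 units for Fgf9 and Six2 in P0 progenitors against P0 non-progenitors, Fos and Foxd1 at 8 days, Ccl2, Ccn2, Cd24a, Cxcl5, Foxc2, Foxd1, Isg15, Lcn2, Pax8 and Sall1 at 19 days, Bmper, Cd24a, Fos, Fosb, Mest, Pax8, Sall1 and Spock2 between the cultures, and Cd24a, S100a6 and Sall1 in 19-day culture against P0 progenitors.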

Other observations

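The choice of genes in this part followed the naming rule, except for the sex-linked genes, which were chosen after seeing the data. Posterior Hox genes, regulators of axial position, were lower after 19 days against E11.5 progenitors. Of the list 4 of 12 measured members fell and 8 did not pass (4 fell adjusted over the list alone, camera adjusted p = 0.006, adjusted p = 0.1 with an estimated correlation), with Hoxd12 18.3-fold lower and Hoxc10 4.54-fold lower. Hoxd12 was also 15.4-fold lower than at 8 days. Genes of FGF and ERK signalling, which supports progenitor survival, were higher at 8 days as a group. In that list 1 of 14 measured members rose and 13 did not pass (1 rose adjusted over the list alone, camera adjusted p = 0.015, adjusted p = 0.2 with an estimated correlation), the member that passed being Dusp6, an ERK phosphatase (1.77-fold higher). Without 1 array the list's call was lost in 2 of 4 fits (median 0.388 to 0.94) and that of Dusp6 in 3. At 19 days the list was not called (camera adjusted p = 0.44), with Etv4 3.65-fold lower and Fosl1 at least 14.3-fold higher.

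Podocyte genes were not called as a group at 8 days (camera adjusted p = 0.66) or 19 days (0.38) against E11.5 progenitors, while single members moved at 19 days, such as Kirrel (12.3-fold higher) and Actn4, an actin cross-linker (2.95-fold higher). Pax8, a relative of Pax2 in the early nephron, was 47.1-fold lower at 19 days against E11.5 progenitors and 34-fold lower than at 8 days. Pax8 read -6.87 and -3.87 on the 19-day arrays, and the calls were lost in 3 and 2 of 4 fits without 1 array, with changes against E11.5 progenitors from -7.059 to -4.055. Of Wnt and beta-catenin targets in P0 against E11.5 progenitors 2 of 14 measured members rose and 12 did not pass (2 rose adjusted over the list alone, camera adjusted p = 0.0087, adjusted p = 0.36 with an estimated correlation), namely Ccnd1 and Tnfrsf19 (5.37-fold higher). Pluripotency genes were called in neither culture against E11.5 progenitors (camera adjusted p = 0.43 at 8 days and 0.59 at 19 days).

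Y-linked genes separated the P0 arrays by replicate number. Ddx3y was -6.24 in P0 progenitors replicate 2 and -6.78 in P0 non-progenitors replicate 2, on the log2 scale relative to the 75th percentile, against 0.0972 and 0.0271 in the replicates numbered 1. Eif2s3y was -6.39 and -6.92 in the replicates numbered 2, and Uty -6.14 and -5.72. On the culture arrays Ddx3y ran from -0.29 to 0.912. Xist was 2.84 and 3.79 in P0 progenitors, 2.28 and 3.66 in P0 non-progenitors, and between 1.00 and 3.98 on the other arrays.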
